A study of Homo sapiens with 6 samples.

How the data were processed

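The data are 6 Illumina HT-12 bead arrays of HCT116 cells, 3 of cells given 0.1% (v/v) DMSO and 3 of cells given 40 µM NU7441, all for 48 h. Per the labels' protocols, total RNA was extracted with an automated kit and biotinylated cRNA was made from it. Per the submitters' processing notes, GenomeStudio, R 3.0.2 and lumi were used. Their order and settings are not given in the sources used here.

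The authors deposited probe signals as linear intensity, not normalized between arrays, with a detection p-value per probe and array per the file headers. The authors also deposited a table of log2 values of the same arrays. Set against the log2 signals after quantile normalization, its values differed by at most 0.068, and each column had a median of 6.22. On brighter probes, each column's deviations from the probe mean correlated at 0.975 or more with those of its own array and at 0.779 or less with those of any other. The scale is thus log2 and not centred, and it was used as an alternative. For 1 probe no value of that table was used.

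The intensity values were background corrected by the normexp model with limma 3.58.1 in R 4.3.3, with the negative controls inferred from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. The offset shrinks the fold changes of dim probes. A probe was kept if its detection p was below 0.05 on all 3 arrays of at least 1 group, which left 14973 of 47323 probes. Probes were named by GEO's platform annotation: 30112 had 1 gene symbol, 8 had several and 17203 had none, and no symbol needed an update through the gene identifiers. A probe without a name is unnamed here, not without a gene. Of the kept probes 2983 had no single name, and 882 of these changed when all kept probes were tested. Each gene was represented by its brightest kept probe over the 6 arrays, which gave 9342 genes. Of 886 changed genes with several kept probes, 8 had changed probes of opposite sign, namely DNAJB6, GPN2, HEATR3, LARP1B, MACROH2A1, N4BP2L2, NR2C2 and TMEM97. No genome build was used and no coordinates are given.

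Differences were tested with lmFit and eBayes of limma, group as the only term, and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. Before the data were examined, 31 gene lists were fixed, of which 30 had at least 5 measured members. They were tested with camera at a preset correlation of 0.01 and adjusted over the 30. With a correlation estimated per list, 13 of the 14 calls held, at much larger camera adjusted p-values. For DNA replication it was 0.0102 in place of 3.27e-16, and for ribosome biogenesis 0.0102 in place of 6.95e-15. The rule for named genes, also fixed then, took the 12 largest rises and the 12 largest falls with arrays that did not overlap, up to 4 changed members of each list with the largest change, and PRKDC, CDKN1A, MDM2, MYC, CCND1, AXIN2, CYP1A1, MKI67 and ABCB1. This gave 130 genes, not all of which are printed. A gene of the rule and a list are not reported here. Other list members named in the text, such as E2F1, H4C3 and CD68, were chosen after their values were seen. Where a list is said to share its counts with those adjusted over the list alone, both counts were equal.

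The procedure was tested on simulated data with the spread of the NU7441 against vehicle comparison over 9342 genes, 200 of them changed. It recovered 2.7% of changes of 0.3 on the log2 scale, 40.3% of changes of 0.5, 90.8% of changes of 1 and 100% of changes of 2. In the data 3592 genes were called, a larger share than was changed in the simulation. The Benjamini-Hochberg cut-off depends on that share, so these rates hold for the simulated setting only. False calls made up 3.42% of calls, and 0% of unchanged lists were called. The simulated noise was independent between genes, and the unchanged lists were run in data without changed genes. The 0% therefore says nothing of false list calls among correlated genes or where many genes change.

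Alternatives were other background corrections and scalings, the authors' log2 table, other detection filters, the mean of a gene's probes, other variance models, array weights, the replicate number as a block, leaving out each array, other list tests, the BET list without the genes shared with the histone list (chosen after seeing the data), an ordinary t statistic and a stricter threshold. The slide as a block was not run because the files do not give the slide. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.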

Results

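HCT116 cells, a human colorectal carcinoma line, were exposed for 48 h to 40 µM NU7441, an inhibitor of the DNA-dependent protein kinase (DNA-PK), or to 0.1% (v/v) dimethyl sulfoxide (DMSO), its vehicle. Total RNA of 3 samples per group was labelled and hybridised to Illumina bead arrays, 1 array per sample. Of 47323 probes, 16593 to 17788 were detected per array, or 35.1% to 37.6%, and the median signal lay between 72.8 and 75.3 on the 6 arrays. The number of arrays limits the precision of every value. The labels do not say whether the 3 samples of a group were separate cultures. The p-values of genes therefore measure the spread between these samples, which may be technical. Camera's p-values at the preset correlation compare a list's genes with the other genes. They do not measure how repeatable a list's change is between samples. The question was which transcripts differ in abundance after 48 h of the inhibitor. All changes are given as log2 fold change of NU7441 over vehicle with the standard error of the fit (SE), n = 3 arrays per group, and adjusted p-values are limma's after Benjamini-Hochberg adjustment over 9342 genes.

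NU7441 changed the level of 3592 of the 9342 genes tested, of which 1747 were higher and 1845 were lower. Genes of DNA replication, ribosome biogenesis, mitosis, homologous recombination and the heat shock response fell. Genes of cholesterol and fatty acid synthesis, lysosomes, antioxidant defence, FOXO and PI3K-inhibition responsive genes, and the listed histone genes rose. The first principal component held 70.9% of the variance and separated the groups. The second held 12% and spread the NU7441 arrays, with replicate 1 at -12.58, replicate 2 at -3.7 and replicate 3 at 15.12. In 4657 genes, or 49.9%, the 3 NU7441 arrays all lay on one side of the 3 vehicle arrays, where chance gives 10%. The median SD within a group was 0.11 for vehicle and 0.14 for NU7441. A change of at least 2-fold was found in 245 genes, 108 higher and 137 lower. Without background correction 46 genes reached it, so fold sizes depend on that step. The share of changed genes that were higher was 48.6%, and 63.2% when arrays were scaled to their 75th percentile.

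**Figure D1:**
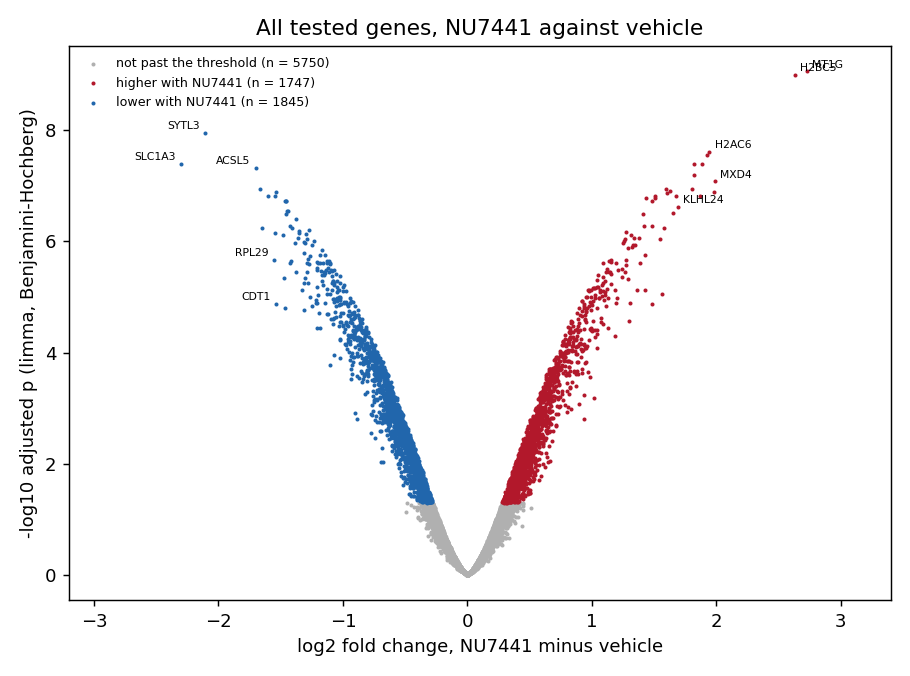
Each point is 1 of the 9342 tested genes, with its log2 fold change (NU7441 minus vehicle) on the horizontal axis and the -log10 of limma's adjusted p on the vertical axis. Red points are the 1747 genes that were higher, blue points the 1845 that were lower, and MT1G lies farthest to the right at 2.73.

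The largest rise was that of MT1G, a metal-binding metallothionein, with a log2 fold change of 2.73 ± 0.11 (SE, adjusted p = 8.76e-10), from a mean log2 intensity of 6.02 ± 0.10 to 8.75 ± 0.12 (SD, n = 3). The histone gene H2BC5 followed at 2.63 ± 0.12 (adjusted p = 1.03e-09). MXD4, a MYC antagonist of the MAX network, rose by 1.99 ± 0.13 (adjusted p = 8.41e-08) and NDRG1, a stress-responsive gene, by 1.87 ± 0.14 (adjusted p = 1.56e-07). GDF15, a secreted stress cytokine, rose by 1.80 ± 0.12 (adjusted p = 1.14e-07). AHNAK2, CLIC3, SMIM14 and KLHL24 were also among the 12 largest rises, at 1.98, 1.83, 1.82 and 1.69. The largest fall was that of SLC1A3, a glutamate and aspartate transporter, at -2.30 ± 0.14 (adjusted p = 4.08e-08). SYTL3, a synaptotagmin-like protein, stood at -2.11 ± 0.11 (adjusted p = 1.13e-08), and ACSL5, a long-chain acyl-CoA synthetase, at -1.70 ± 0.11 (adjusted p = 4.76e-08). PRKACB, a catalytic subunit of protein kinase A, and MLKL, the effector of necroptosis, were at -1.66 and -1.65. GAL, PLD6, HS3ST1 and SEPTIN3 completed the largest falls outside the gene lists, between -1.55 and -1.48.

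PRKDC, which encodes the catalytic subunit of DNA-PK, did not pass the threshold, with -0.38 ± 0.18 (adjusted p = 0.102). Its NU7441 arrays read 7.51, 7.60 and 6.73 against a vehicle mean of 7.66 ± 0.09 (SD, n = 3), and the adjusted p was 0.0465 without NU7441 replicate 1 and 0.0361 without NU7441 replicate 2. Of its 3 dimmer probes, 1 was past the threshold when all kept probes were tested, at -0.41 ± 0.15 (limma adjusted p = 0.0456), and the others were at -0.24 and 0.08. MYC, a transcription factor of growth genes, fell by 0.92 (SE 0.12, adjusted p = 2.47e-05). CDKN1A, the cyclin-dependent kinase inhibitor p21, was at 0.44 ± 0.16 (adjusted p = 0.0337), with overlapping arrays. Its adjusted p was 0.133 without vehicle replicate 1, 0.0778 without vehicle replicate 3, 0.117 without NU7441 replicate 1 and 0.141 without NU7441 replicate 2. It was 0.15 with no detection filter. CCND1, cyclin D1, stood at -0.38 ± 0.11 (adjusted p = 0.0121), and at an adjusted p of 0.0678 with 75th percentile scaling. MKI67, at -0.16 ± 0.13 (adjusted p = 0.325), was detected on 2 of 3 vehicle arrays. The efflux pump gene ABCB1 was at 0.07 ± 0.12 (adjusted p = 0.652), with log2 intensities near background. MDM2 and CYP1A1 were not tested because no probe passed the detection filter.

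**Figure D2:**
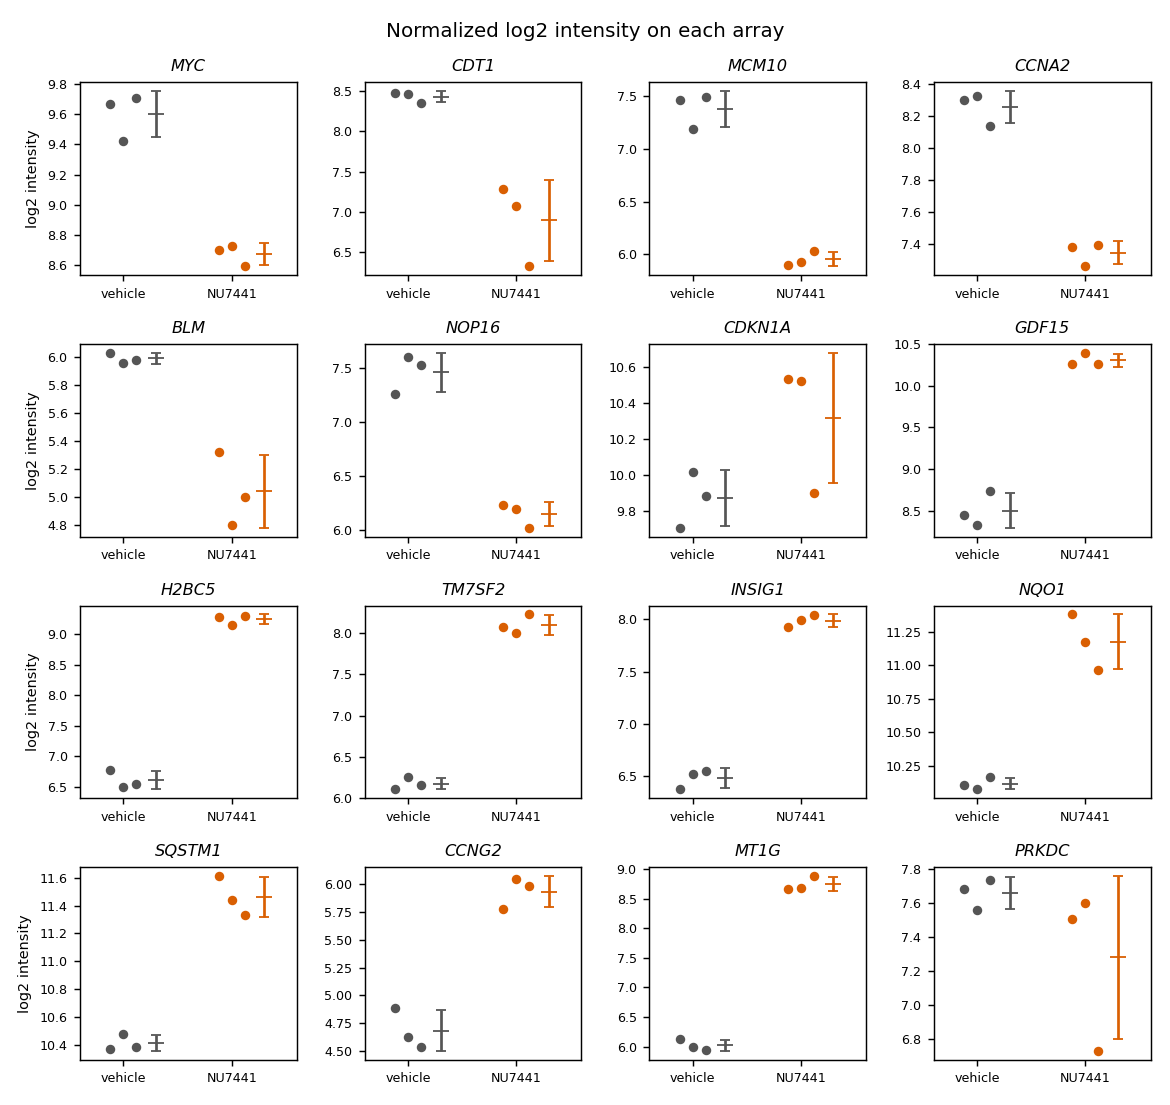
Normalized log2 intensity of 16 named genes on each array, with the 3 vehicle arrays in grey and the 3 NU7441 arrays in orange, each panel on its own vertical axis. Points are arrays and the bar beside them is the mean with its SD, and the NU7441 arrays of PRKDC and CDKN1A overlap those of vehicle.

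DNA replication and G1/S genes fell as a group. Of 41 measured, 34 were lower and 1 was higher, or 35 and 1 adjusted over the list alone, with a median of -0.74 (camera adjusted p = 3.27e-16). The fall included E2F2, a transcription factor of S-phase entry, at -1.60 ± 0.12 (adjusted p = 1.56e-07), and CDT1, a replication licensing factor, at -1.54 ± 0.18 (adjusted p = 1.33e-05). POLE2, a subunit of DNA polymerase epsilon, was at -1.46 and the initiation factor MCM10 at -1.43. E2F1 was the member that rose, at 0.49. The G2/M and mitosis list fell with 36 lower and 1 higher of 49, or 41 and 1 adjusted over the list alone, and a median of -0.47 (camera adjusted p = 3.56e-11). SPC25, a kinetochore protein, CDC20, an activator of the anaphase-promoting complex, and CCNA2, cyclin A2, were at -0.93, -0.91 and -0.91. A dimmer probe of SPC25, at -0.14, did not pass when all kept probes were tested. BIRC5, survivin, was at -0.87.

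Homologous recombination and Fanconi anaemia genes fell, with 17 lower and 1 higher of 21, or 18 and 1 adjusted over the list alone, and a median of -0.54 (camera adjusted p = 3.02e-07). EXO1, a nuclease of DNA end resection, was at -1.27 ± 0.11 (adjusted p = 6.23e-07), RAD51AP1 at -1.24, FANCG at -1.14 and the helicase gene BLM at -0.95. The count of higher members was 0 without vehicle replicate 1 or 2, without NU7441 replicate 2 or 3 and with no detection filter. The non-homologous end joining list, the pathway of DNA-PK, was not called, with 4 lower and 1 higher of 14, or 3 and 1 adjusted over the list alone, and a camera adjusted p of 0.705. The count of lower members was 1 without vehicle replicate 2, 2 without vehicle replicate 3 and 1 with 75th percentile scaling. The count of higher members was 0 without any 1 of the vehicle arrays, without NU7441 replicate 2 or 3, with no detection filter and in the submitters' table. It was 3 without NU7441 replicate 1, and 2 with array weights or 75th percentile scaling. XRCC5, which encodes Ku80, was at -0.52 ± 0.11 (adjusted p = 0.00244). The list of PI3K-like kinases holds PRKDC and ATM beside lipid kinases and their regulatory subunits, so it is wider than the family of DNA-PK. In it 3 members were higher and 1 lower of 13, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.49). Its lower count was 0 without vehicle replicate 2 or 3, without NU7441 replicate 3 and in 6 other alternatives, among them 75th percentile scaling, and 2 without NU7441 replicate 2. PIK3C2A rose by 0.51 and ATM, the double-strand break kinase, by 0.46. Their second probes, at 0.17 and 0.33, did not pass when all kept probes were tested.

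Ribosome biogenesis and MYC-regulated nucleolar genes fell, with 34 lower and 0 higher of 38, or 35 and 0 adjusted over the list alone, and a median of -0.68 (camera adjusted p = 6.95e-15). NOP16, MRTO4 and RRS1, ribosome assembly factors, were at -1.31, -1.21 and -1.15, and the nucleolar protein NOLC1 was at -1.13. Without NU7441 replicate 3, 1 member was higher. Of 39 cytosolic ribosomal proteins, 4 were higher and 1 was lower, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.603). RPL14 was at 0.73 and RPL29 at -1.56 ± 0.15 (adjusted p = 2.18e-06), the latter with a second probe at -1.54. With 75th percentile scaling 12 members were higher and the list's adjusted p was 0.0162, and 8 were higher without background correction. The lower count was 4 with the mean of a gene's probes, and 2 without background correction or in the submitters' table.

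The heat shock list fell, with 11 lower and 1 higher of 17, or 12 and 1 adjusted over the list alone, and a median of -0.42 (camera adjusted p = 0.000276). FKBP4, a co-chaperone of HSP90, was at -0.92 ± 0.12 (adjusted p = 4.01e-05), CHORDC1 at -0.82, the mitochondrial chaperonin HSPE1 at -0.77 and the constitutive chaperone HSPA8 at -0.76. With detection below 0.01 asked on all 6 arrays, 0 members were higher.

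Replication-dependent histone genes rose. Of 10 measured from 33 in the list, 8 were higher and 1 was lower, also adjusted over the list alone, with a median of 1.09 (camera adjusted p = 7.72e-07). After H2BC5, H2AC6 stood at 1.94 ± 0.11 (adjusted p = 2.5e-08), H2AC18 at 1.89 ± 0.12 (adjusted p = 4.08e-08) and H4C14 at 1.26. H4C3 was the member that fell, at -0.92. The median was 0.56 without background correction, and 5 members were higher when detection below 0.01 was asked on all 6 arrays. Histone genes outside the list, looked at after the values were seen, went several ways. H2AC19, H2AJ, H2AC25, H2AC20, H4C15, H1-10 and H3-3B were higher, at 1.65, 1.32, 1.20, 1.12, 0.82, 0.36 and 0.31. The lower ones were variants that are not replication-dependent, MACROH2A2, H2AZ1 and MACROH2A1, at -0.98, -0.45 and -0.39. MACROH2A1 also had changed probes of opposite sign. No replication-dependent gene outside the list was lower. H2AC17, H3C7, H3C13 and H4C12, among others, did not pass the threshold, at 0.21, 0.09, 0.07 and 0.03. The list of genes known to respond to bromodomain (BET) inhibitors was called higher, with 8 higher and 2 lower of 12, or 9 and 2 adjusted over the list alone, and a median of 0.55 (camera adjusted p = 0.000712). Its genes, MYC among them, were not split by the direction of their known response. A call of higher, or its loss, therefore does not say whether the change resembles that of BET inhibitors. The BET list shares 5 genes with the histone list, 4 of them measured, and the call was lost without them. The 8 members measured outside the histones held 4 higher and 2 lower, with a median of 0.37 (camera adjusted p = 0.351, and an adjusted p of 0.444 with an estimated correlation), a subset chosen after seeing the data. SAT1, a polyamine-catabolising enzyme outside the histones, was at 1.05.

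Cholesterol biosynthesis genes rose, with 13 higher and 0 lower of 17, also adjusted over the list alone, and a median of 0.72 (camera adjusted p = 4.92e-08). TM7SF2, a sterol reductase, was at 1.92 ± 0.11 (adjusted p = 2.79e-08), MSMO1 at 1.58, IDI1 at 1.56 and INSIG1, a regulator of SREBP processing, at 1.51. Fatty acid synthesis genes rose with 10 higher and 1 lower of 16, or 11 and 1 adjusted over the list alone, and a median of 0.41 (camera adjusted p = 0.000456). LPIN1, a phosphatidate phosphatase, was at 1.35 and ACSS2, an acetyl-CoA synthetase, at 1.09. Without NU7441 replicate 3, 2 members were lower. Lysosome and autophagy genes rose with 18 higher and 0 lower of 31, or 22 and 0 adjusted over the list alone, and a median of 0.45 (camera adjusted p = 6.35e-08). NEU1, a lysosomal sialidase, was at 1.34 ± 0.12 (adjusted p = 8.82e-07), and the autophagy genes MAP1LC3B, GABARAPL1 and SQSTM1 were at 1.24, 1.21 and 1.05.

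NRF2 antioxidant genes rose, with 13 higher and 1 lower of 20, also adjusted over the list alone, and a median of 0.69 (camera adjusted p = 3.37e-06). ABCC3, an efflux transporter, was at 1.44 ± 0.11 (adjusted p = 1.68e-07), GCLC, a subunit of the rate-limiting enzyme of glutathione synthesis, at 1.15, NQO1, a quinone reductase, at 1.06 and TXNRD1, thioredoxin reductase, at 1.04. The FOXO and PI3K-inhibition list rose with 16 higher and 2 lower of 25, also adjusted over the list alone, and a median of 0.40 (camera adjusted p = 0.000121). BCL6, PINK1 and CCNG2 were at 1.38, 1.26 and 1.25. The list's higher members numbered 10 without vehicle replicate 2 and 10 without vehicle replicate 3.

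The hypoxia and glycolysis list was called higher (camera adjusted p = 0.0247), with 14 higher and 5 lower of 34, or 15 and 6 adjusted over the list alone, and a median of 0.19. The call was lost with an adjusted p of 0.251 with an estimated correlation, 0.0666 with 75th percentile scaling and 0.0548 without NU7441 replicate 1. The count of lower members was 2 without vehicle replicate 1, 2 without vehicle replicate 3, 3 without NU7441 replicate 2 and 2 with 75th percentile scaling. Besides NDRG1, ANGPTL4 was at 1.13 and the mitophagy receptor BNIP3L at 1.07. A dimmer probe of ANGPTL4, at 0.28, did not pass when all kept probes were tested. HK2 fell, at -1.18 ± 0.16 (adjusted p = 3.66e-05), and was detected on 1 of 3 NU7441 arrays. Its second probe was at -0.34. With any 1 of the vehicle arrays left out, that second probe was the brighter and stood for HK2. It did not pass, at -0.36, -0.35 and -0.30 without vehicle replicate 1, 2 and 3. The lost call thus came with a change of probe, and the first probe was not followed there. The calls of the other lists reported as called held with an estimated correlation, at adjusted p of at most 0.044.

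The remaining lists were not called by camera. In the ATF4 list 11 members were higher and 3 lower of 31 (camera adjusted p = 0.053), led by PCK2 at 1.00 and DDIT4 at 0.99, with the same counts adjusted over the list alone. Its lower count was 1 without any 1 of the vehicle arrays, without NU7441 replicate 1 or 3, and with array weights. In oxidative phosphorylation 2 were higher and 11 lower of 41 (camera adjusted p = 0.0677), also adjusted over the list alone, with ATP5MC1 at -0.84. The lower count was 6 without vehicle replicate 1, 7 without vehicle replicate 2, 7 without vehicle replicate 3 and 6 with 75th percentile scaling. Of 19 interferon-stimulated genes 6 were higher and 2 lower (camera adjusted p = 0.0845), also adjusted over the list alone, with IRF7 at 1.55 and IFIT1 at -0.66. With 75th percentile scaling 10 were higher. The lower count was 1 without any 1 of the vehicle arrays, without NU7441 replicate 3 and in 6 other alternatives, among them 75th percentile scaling. Of 14 TGF-beta responsive genes 4 were higher and 2 lower (camera adjusted p = 0.108), also adjusted over the list alone, with BHLHE40 at 1.12 and CCN1 at -0.73. Of 15 Wnt targets 3 were higher and 7 lower, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.184). DKK1, a secreted Wnt antagonist, was at -1.46, and AXIN2 was at 0.29 ± 0.11 with an adjusted p of 0.0561. The adjusted p of AXIN2 was 0.034 without NU7441 replicate 1 and between 0.0233 and 0.0495 in 7 other alternatives. With the mean of a gene's probes 5 Wnt targets were higher.

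Of 27 ERK-responsive genes 4 were higher and 11 lower, or 5 and 12 adjusted over the list alone (camera adjusted p = 0.184). JUN was at 1.09, and EREG and SPRY1 were at -1.05 and -1.07. The higher count was 2 without vehicle replicate 1 and 2 with no detection filter, and the lower count 7 with 75th percentile scaling. Of 12 NF-kappaB genes 5 were higher and 3 lower (camera adjusted p = 0.245), also adjusted over the list alone, with CXCL8, interleukin 8, at 1.19. Without vehicle replicate 2, 3 were higher and 1 was lower, and 1 was lower with 75th percentile scaling. Of 22 apoptosis regulators 4 were higher and 5 lower (camera adjusted p = 0.827), also adjusted over the list alone, with PMAIP1 at 0.48 and BID at -0.59. A dimmer probe of BID, at -0.24, did not pass when all kept probes were tested. The lower count was 3 without vehicle replicate 3, and 3 with 75th percentile scaling, without background correction or in the submitters' table. Of 25 unfolded protein response genes 3 were higher and 4 lower (camera adjusted p = 0.993), also adjusted over the list alone, with SDF2L1 at -1.08, and camera and fry gave this list opposite signs. With 75th percentile scaling 5 were higher. Of 11 xenobiotic genes 3 were higher and 3 lower (camera adjusted p = 0.793), and of 7 aryl hydrocarbon receptor targets 2 were higher and 3 lower (camera adjusted p = 0.823), both also adjusted over the list alone. The lower count of the latter was 1 without vehicle replicate 1 or 2 and without NU7441 replicate 1. Of 15 genes of epithelial-mesenchymal transition 2 were higher and 0 lower (camera adjusted p = 0.793), also adjusted over the list alone, with a median of -0.05 and a mean of 0.05. The members that rose were ACTA2, a mesenchymal marker, at 0.76 and CDH1, E-cadherin, an epithelial marker, at 0.52. The list joins markers of both states, which a transition would move in opposite directions. Its test therefore cannot say whether a transition took place. With 75th percentile scaling 4 were higher. The lower count was 1 without NU7441 replicate 3 or with array weights, and 2 with the mean of a gene's probes. Of 5 intestinal markers 1 was higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.827). The lower count was 0 without any 1 of the vehicle arrays, without NU7441 replicate 2 and with no detection filter, and 2 without NU7441 replicate 3. Of 30 markers of fibroblasts, endothelium and immune cells 2 were measured, COL1A1 at 0.13 and CD68 at 0.11, neither past the threshold, and the list was not tested.

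**Figure D3:**
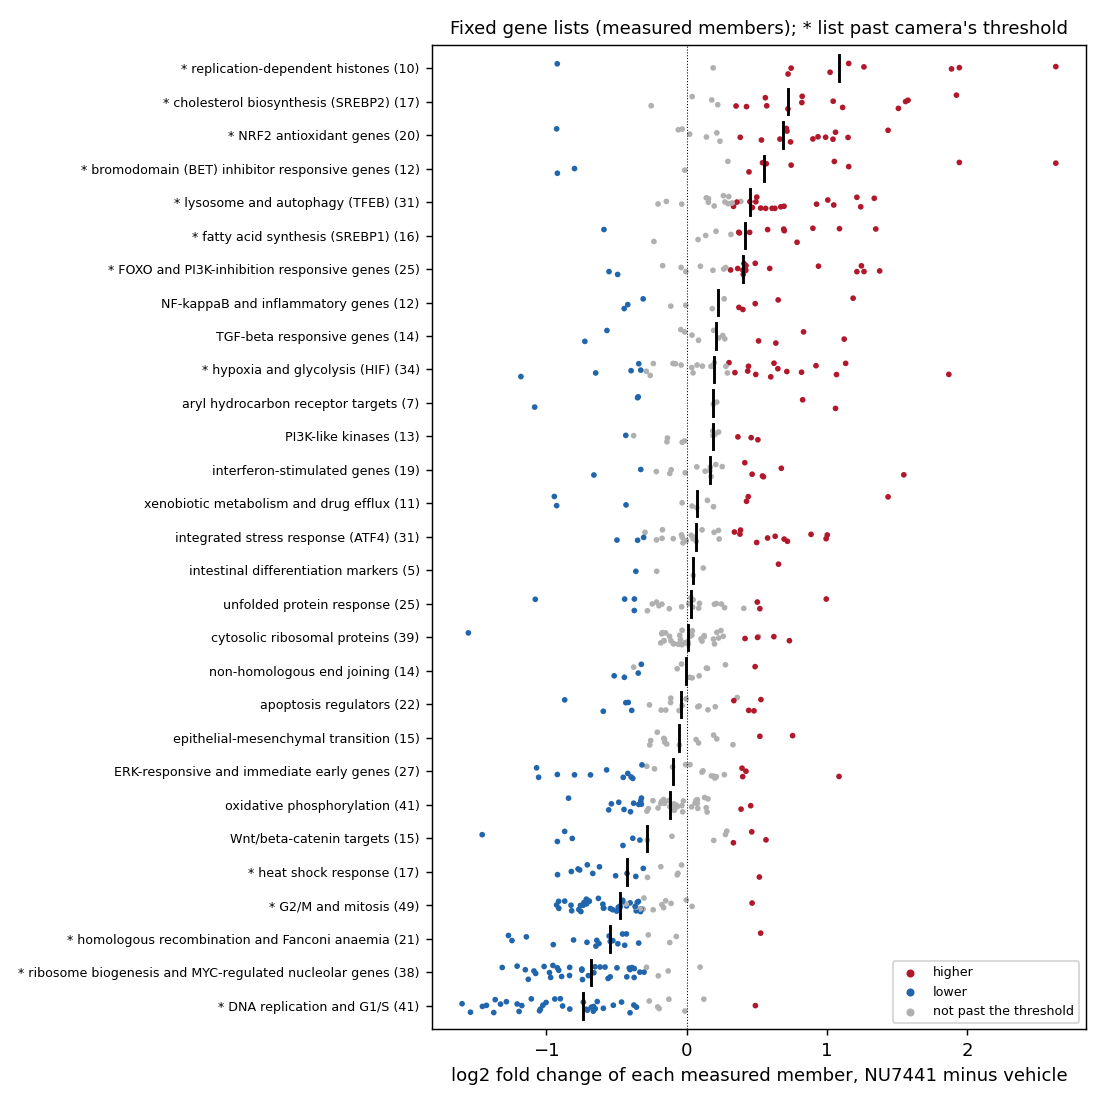
Log2 fold change (NU7441 minus vehicle) of every measured member of 29 of the tested gene lists, with members that were higher in red, lower in blue and not past the threshold in grey, and the list's median as a black line. Lists are ordered by their median, from -0.74 in DNA replication to 1.09 in the histones, and an asterisk marks the 13 of them past camera's threshold.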

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

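The numbers of changed genes were within 1.5 times their main values in all alternatives except these. With a threshold of 0.01, 2278 genes changed (1058 higher, 1220 lower), and with an ordinary t statistic 2060 (936 higher, 1124 lower), against 3592 in the main analysis. Genes changed at least 2-fold numbered 245, but 46 without background correction and 52 in the submitters' table. The setting without background correction differed from the main analysis only in that step and its offset. The submitters' values lay within 0.068 of the same uncorrected signals after quantile normalization, so the 2 settings are not independent. For the ordinary t statistic the cause was not tested. Leaving out 1 array gave 2762 to 3653 changed genes. Of the 3592 genes, 3060 were also called without background correction and 3101 with 75th percentile scaling, with the same sign in each. Replicate numbers did not pair the samples, since deviations of same-numbered arrays correlated at -0.102, 0.035 and -0.07. With the replicate number as a block, 3494 genes changed (1702 higher, 1792 lower).

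Of 30 lists, 20 kept their call in every alternative, and no list reversed. The BET list lost its call (0.351) without the genes shared with the histone list, an alternative chosen after seeing the data. For the other 9, the cause was not tested. The hypoxia list lost its call with 75th percentile scaling (0.0666) and estimated correlation (0.251), and ranged from 0.00711 to 0.0548 with an array left out. Ribosomal proteins gained one with 75th percentile scaling (0.0162). With fry, which does not compare a list with other genes, calls were gained for Wnt (0.00243), ATF4, interferon and TGF-beta (each 0.0105), oxidative phosphorylation and ERK (each 0.00169) and NF-kappaB (0.0495). ATF4 also passed without background correction (0.0477), in the submitters' table (0.0471), with no detection filter (0.0134), with the mean of probes (0.0428), with trend and robust variance (0.0393) and with array weights (0.0274), and ranged from 0.0296 to 0.081 with an array left out, passing without vehicle replicate 1, vehicle replicate 3 or NU7441 replicate 3. Oxidative phosphorylation passed without background correction (0.0147), in the submitters' table (0.0153), with no detection filter (0.00199) and with trend and robust variance (0.0366), with a range of 0.0404 to 0.106. TGF-beta passed without background correction (0.0491), in the submitters' table (0.0471) and with no detection filter (0.0355), with a range of 0.0404 to 0.256. Interferon ranged from 0.0473 to 0.181. Leaving out NU7441 replicate 3 gave the values below the threshold for oxidative phosphorylation, TGF-beta and interferon. Of 130 named genes, 117 kept their call in the 16 alternatives in which named genes were compared, where they had a value, and none reversed. The threshold of 0.01 and the ordinary t statistic were not among those 16. Over all genes these 2 kept 63.4% and 53.8% of the main calls. Signal near background limits the values of dim genes.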

Other observations

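Families in the first paragraph, the tests of small nucleolar RNAs, of histone families and of unequal change of the cell cycle lists were chosen after the results were seen. Of 7 families so chosen, with p-values adjusted over the 7, 3 were called, and small nucleolar RNAs (lower, camera adjusted p = 0.126), long noncoding RNAs (0.247), transcribed pseudogenes (0.0835) and zinc finger genes (0.585) were not. Small nuclear RNAs, the RNA parts of the spliceosome and related particles, rose, with 7 higher and 1 lower of 10 and a median log2 fold change of 0.94 (camera adjusted p = 2.09e-05, and an adjusted p of 0.0493 with an estimated correlation). RN7SK, which holds the elongation factor P-TEFb inactive, was at 1.51 ± 0.11 (SE, n = 3 per group, limma adjusted p = 1.66e-07), and the U1 gene RNU1-3 at 1.41 ± 0.11 (adjusted p = 3.22e-07). The U1 genes are near-identical, so their probes are not independent. SNAR-A1 was the member that fell, at -0.93. Small Cajal body RNAs had 7 higher and 1 lower of 11 (camera adjusted p = 0.00384), a call lost with an adjusted p of 0.0913 with an estimated correlation. Metallothioneins rose, with 4 higher and 0 lower of 6 and a median of 0.92 (camera adjusted p = 0.000147, and an adjusted p of 0.0493 with an estimated correlation). Besides MT1G, MT1X was at 1.63, MT2A at 1.19 and MT1E at 0.65, and MT1F at 0.03 did not pass. Copies of this family are alike in sequence, so a probe may read more than its own gene, which was not tested (the median change was 0.91 without background correction). The medians of the 3 called families were positive under all 4 other scalings and background settings. That of the small Cajal body RNAs fell from 0.56 to 0.19 without background correction and 0.18 in the submitters' table, and that of the small nuclear RNAs from 0.94 to 0.66 and 0.68.

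In RPS7, which is outside the fixed list, the log2 fold change was -1.45 ± 0.11 (SE, limma adjusted p = 2.81e-07), close to that of RPL29. It was chosen after its value was seen.

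The main comparison called 3592 genes, and the highest of the other splits of the 6 arrays called 0. The real split was thus 1 of 10 with a result as large, and 10 splits are too few for a share under 0.05.

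Histone genes of the fixed list rose while DNA replication genes fell. Outside the list, replication-dependent histone genes were higher or not past the threshold, and the lower genes were other variants. What that says of the causes below was not tested. For normalization between arrays, the histone median was 1.0887 in the main analysis, 1.1817 with 75th percentile scaling and 1.087 with cyclic loess. The median of all genes was 0.0022, 0.0948 and -0.0039 in the same order. Scalings this close could hardly bring the histone median to 0. The values thus argue only against the choice among these scalings as the cause, and normalization as such stays open. The lowest median over the main and 4 other settings was 0.5565, without background correction. It stayed above 0, though close to the bound of 0.5 set before. That setting and the submitters' table (0.5567) are both close to quantile-normalized uncorrected signals. They thus bear on background correction and not on the scaling. A larger share of RNA without a poly(A) tail in the labelled RNA would raise small nucleolar RNAs too, but their median over 82 was -0.164 (95% bootstrap interval over genes -0.206 to -0.1131), and -0.09 in the 11 of them brighter than the median gene, and the median over all 82 moved to -0.023 with 75th percentile scaling, -0.0655 without background correction and -0.0633 in the submitters' table, each below the bound of 0.5. That argues against such a share as the sole cause, but the rise of small nuclear RNAs (median 0.94) and of 8 small nucleolar RNAs (17 fell), such as SNORA12 at 1.43, goes with it, as does the weaker rise of small Cajal body RNAs (median 0.56, or 0.18 in the submitters' table, with the call lost at an estimated correlation), and a separate fall of other small nucleolar RNAs could hide it. The risen members of the histone list came from 4 histone families, which argues against 1 transcript read by all their probes, while reading between near-identical copies within a family, and a change of histone transcripts in cells given NU7441, stay open and untested.

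Replication genes fell more than mitotic genes. The difference of the changes in their array means was -0.2961 (SE 0.0237, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). That value is the pattern itself, and how far each list depends on cycling cells was not measured, so a lower share of cycling cells stays open. Compression of dim probes was argued against by 34 pairs of genes matched within 0.5 of vehicle level, where the difference was -0.2714 (SE 0.0072, exact two-sided permutation p = 0.1). Neither a move of cells between phases nor a direct effect of NU7441 on G1/S transcripts was tested.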
